A study of Homo sapiens with 12 samples.

How the data were processed

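RNA was sequenced from 2 human pancreatic carcinoma lines, MIA PaCa-2 and PANC-1, each transfected with a control siRNA or with a mixture of 2 siRNAs against RBM3. Per the labels' protocols, the siRNA concentration was 25 nM, transfection followed 72 h of culture and lasted 4.5 h, and cells were collected after an overnight recovery. There were 12 libraries in 4 groups of 3, made with an Illumina TruSeq kit and read from both ends at 75 bp, per the labels' protocols. The labels give both total RNA and cytoplasmic RNA as the material, and they name 2 media without saying which line grew in which. They do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

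The deposited values are raw read counts per Ensembl gene identifier in 1 table of all libraries, without normalisation. Per the submitters' processing notes, the tools were STAR 2.5.2a, Picard, featureCounts and Subread, and the build was hg19/GRCh37. The annotation release, the strand setting and whether duplicate reads were counted are not given in the sources used here. Duplicate treatment could change the counts of abundant transcripts, and without a known strand setting, reads of overlapping or antisense genes cannot be told apart. Reads shared with a near-identical copy, as between MORF4L1 and its pseudogene MORF4L1P1, could be split either way. The reference annotation used here is of another build, so it served for gene type, gene order and untranslated regions, and no coordinates are given.

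The table held 63677 gene rows. A gene name table matched 52181 of them and gave a symbol for 39699. Before the data were examined, rows naming no gene were to be left out. All rows carried an identifier, so this was read as blank or summary rows and none was removed. Genes without a symbol held between 1.02% and 1.33% of the counts of a library, and a fit on genes with a symbol, added after the data were seen, called the same 2 genes in MIA PaCa-2. Total counts ranged from 14217185 to 39652502 per library, and 3 counts, the limit that a count of 0 allows, correspond to between 0.0757 and 0.211 CPM. Intervals and limits cover counting error only.

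Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by the two-sided quasi-likelihood F-test after TMM normalisation and the filterByExpr filter with its minimum count of 10, which left 17862 genes. All 12 libraries entered 1 model of group means with 8 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The contrasts were RBM3 siRNA against control siRNA in each line, the difference between those responses, and PANC-1 against MIA PaCa-2 under control siRNA. The SE printed with an edgeR log2 fold change, in the text and in the figures, is an approximation. It is the absolute log2 fold change divided by the square root of the F statistic of its test. Expression is given as TMM-normalised CPM (counts scaled to library size), as mean ± SD over 3 libraries unless another n is stated. Gene lists were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. Of 29 lists fixed before the data were examined, 25 had at least 5 tested members.

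The genes named were RBM3, PRR11 and SKA2 in each comparison. To these were added up to 10 genes per direction in each line among those past the threshold, at 2 CPM or more, with all siRNA libraries beyond all control libraries, or the 5 smallest p-values where none passed. Under control siRNA they were the 5 genes past the threshold with the largest log2 fold change in each direction at 10 CPM or more, and in each list the 4 members with the smallest p. For the difference between the lines the rule gave the 5 smallest p-values. The genes called by DESeq2 and those used to describe single libraries are also named, a choice made after their values were seen.

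Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, median-of-ratios size factors, library size alone, no filter, a filter of 1 CPM in 6 libraries, each line alone, the replicate number as a block, other thresholds and the removal of each library in turn. Added after seeing the data were genes with a symbol alone, DESeq2 without PANC1_siRBM3 replicate 3, a model that also sets apart a pair of PANC-1 libraries, limma-voom with sample weights, the log2 total count as a covariate, and gene lists under an estimated correlation without PANC1_siRBM3 replicate 3. Replicates of a group were compared in pairs, and the chi-square per degree of freedom of their counts was between 11.7 and 184, so no library was a copy of another in its group; libraries of different groups were not compared in this way.

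The tests were run on simulated counts for 17862 genes with known changes, 3 times. In the MIA PaCa-2 comparison edgeR found 36.3% of the genes changed 2-fold and 94.7% of those changed 4-fold, and 7.03% of its calls were false. For PANC-1 these were 34.0%, 96.0% and 4.41%. False calls made up 20.6% of those of DESeq2 for MIA PaCa-2 and 20.7% for PANC-1, above its nominal level, and 10.9% and 7.28% of those of limma-voom. Such shares depend on the number of changes planted, and genes were drawn independently of each other. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for sequence counts, tables and figures.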

Results

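Transcript levels were measured by RNA sequencing in MIA PaCa-2 and PANC-1, established human pancreatic carcinoma cell lines, with and without siRNA against RBM3, a cold-inducible RNA-binding protein. Each of the 4 groups held 3 libraries. Total counts were 39652502, 16094995 and 16300386 in MIA PaCa-2 control replicates 1, 2 and 4, and 26017058, 33358837 and 17861847 in RBM3 siRNA replicates 1, 2 and 5. In PANC-1 they were 23993638, 14217185 and 21117562 in control replicates 1, 2 and 4, and 32564458, 33341322 and 31440551 in siRNA replicates 1, 2 and 3. The study's purpose was to find genes that depend on RBM3 in these lines, and its title singles out PRR11, a proline-rich protein linked to cell cycle progression. PRR11 was chosen by the study on these samples, so its values are not independent evidence of its direction.

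The siRNA target was lower in all siRNA libraries than in all control libraries of its line. In MIA PaCa-2, RBM3 was at 244 ± 35.3 CPM with control siRNA and 47.9 ± 12.6 CPM with RBM3 siRNA (SD, n = 3), or 19.6% of the control level. In PANC-1 it was at 476 ± 78.8 CPM and 125 ± 60.9 CPM (SD, n = 3), or 26.2%. The two-sided exact permutation p was 0.1 in both lines, the smallest that 3 against 3 libraries allow. The edgeR log2 fold change was -2.35 (SE 0.31) in MIA PaCa-2, with an adjusted p of 0.0426. In PANC-1 it was -1.93 (SE 0.30) with an edgeR adjusted p of 0.516. DESeq2 gave 5.29e-09 and 1.75e-05 as the adjusted p of the same comparisons.

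**Figure D1:**
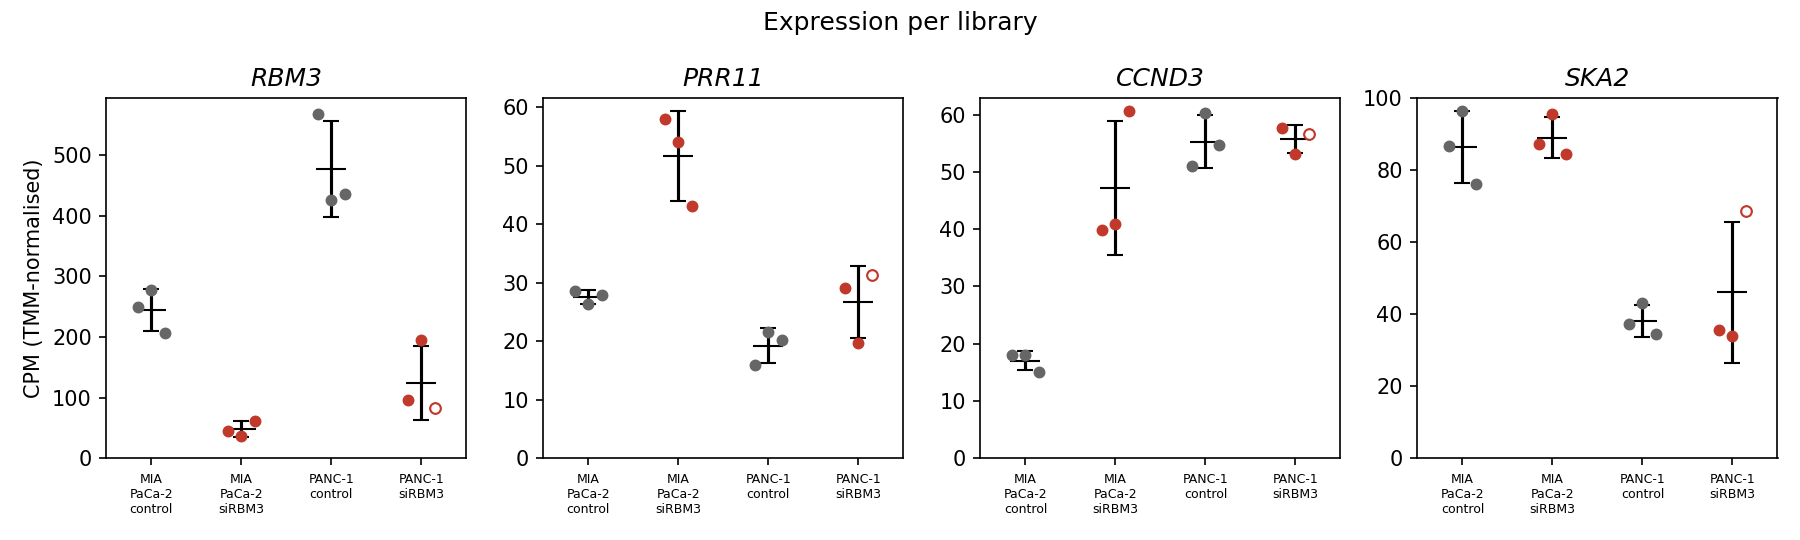
Expression of RBM3, PRR11, CCND3 and SKA2 in TMM-normalised CPM (vertical axes, from 0) in each library of the 4 groups, with control siRNA in grey and RBM3 siRNA in red; the bar and whiskers are the mean ± SD of 3 libraries and the open symbol is PANC-1 siRNA replicate 3. RBM3 is lower in every siRNA library of both lines, and CCND3 is at 47.1 against 17.1 CPM in MIA PaCa-2 and at 55.8 against 55.3 CPM in PANC-1.

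In MIA PaCa-2, CCND3, which encodes the G1-phase cyclin D3, rose with RBM3 siRNA from 17.1 ± 1.71 to 47.1 ± 11.7 CPM (SD, n = 3), higher in all 3 siRNA libraries. Its edgeR log2 fold change was 1.46 (SE 0.19) with an adjusted p of 0.0426. RBM3 and CCND3 were the 2 genes that passed among 17862 tested. PRR11 was at 27.6 ± 1.14 CPM with control siRNA and 51.7 ± 7.72 CPM with RBM3 siRNA (SD, n = 3), with no overlap of the libraries and an exact permutation p of 0.1. Its log2 fold change was 0.91 (SE 0.21), with an adjusted p of 0.782 in edgeR and 0.0312 in DESeq2. SKA2, a kinetochore gene that lies head to head with PRR11, was at 86.4 ± 10.1 and 89.0 ± 5.79 CPM (SD, n = 3).

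At an unadjusted p under 0.05 edgeR gave 525 genes in MIA PaCa-2, fewer than the 893 that chance would give. DESeq2 called 21 genes there and limma-voom 1, RBM3. Both edgeR calls were lost when any 1 library other than PANC1_siRBM3 replicate 2 or 3 was left out, each giving 0 genes. Median-of-ratios size factors in place of TMM also gave 0 genes, with an edgeR adjusted p of 0.0543 for RBM3. In a fit of the MIA PaCa-2 libraries alone edgeR called RBM3 and PDS5A. There the PDS5A log2 fold change in MIAPaCa2 was -1.35 with an edgeR adjusted p of 0.0437, and the CCND3 log2 fold change in MIAPaCa2 was 1.46 with an edgeR adjusted p of 0.281, so that call was lost. Over the 12 removals the edgeR adjusted p ran from 0.00120 to 0.548 for RBM3 and from 0.0301 to 0.380 for CCND3.

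The 9 genes called higher by DESeq2 in MIA PaCa-2 included CCND3 and PRR11. Others were MCFD2, part of a cargo receptor between endoplasmic reticulum and Golgi, SRPRA, a subunit of the signal recognition particle receptor, BANF1, a DNA-binding protein of the nuclear envelope, and the histone gene H3-3A. The 12 called lower included PDS5A, a cohesin regulator, MORF4L1, a chromatin protein, SCARB2, a lysosomal membrane protein, and PRKAG2, a subunit of the AMP-activated kinase. PDS5A had an edgeR log2 fold change of -1.34 (SE 0.20), MORF4L1 -0.93 (SE 0.16), MCFD2 1.04 (SE 0.18) and SMAP1 1.03 (SE 0.18). The remaining calls were EPB41L1 and PPP2R1B (higher), and RNF14, NIPSNAP3A, FYCO1, HIF1AN, PIGN, SH3D21 and the pseudogene MORF4L1P1 (lower). In simulated counts for this comparison 20.6% of the DESeq2 calls were false, or 137 of 664 over 3 simulations. Many changes were planted there and genes were drawn independently of each other. The share of false calls among the 21 here may therefore differ and was not estimated.

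Of the 25 gene lists tested in MIA PaCa-2, camera called 7 at its preset correlation. Amino acid and stress response targets of ATF4 had a median log2 fold change of -0.35, with 20 of 24 members negative (adjusted p 6.74e-05 by camera in limma), among them CHAC1 at -1.44 (SE 0.75) and CEBPB at -0.53 (SE 0.23). The interferon response list had a median of -0.41, with 26 of 28 negative (limma camera adjusted p 7.25e-05), among them IFI44 at -1.13 (SE 0.39) and OAS2 at -1.04 (SE 0.62). DNA repair genes had a median of -0.16, with 28 of 32 negative (limma camera adjusted p 0.00677), and p53 targets one of -0.17, with 17 of 21 negative (0.0430), including MDM2 at -0.64 (SE 0.19). On the positive side were mitosis genes, with a median of 0.13 and 31 of 34 positive, including KIF23 at 0.35 (SE 0.16). Oxidative phosphorylation genes had a median of 0.11 and 29 of 38 positive, including COX6C at 0.47 (SE 0.18), and ribosomal protein genes one of 0.09 and 50 of 57 positive. The limma camera adjusted p of these was 0.00831, 0.00861 and 0.00998. With an estimated correlation no list was called, and the limma camera adjusted p was 0.580 for p53 targets and 0.888 for each of the other 6. No member of any list passed in edgeR, either over all genes or adjusted over the list alone. Without MIAPaCa2_control replicate 1 the preset test called 0 lists, and the direction turned upward for the interferon and DNA repair lists (limma camera adjusted p 0.739 and 0.839) and downward for ribosomal proteins (0.110). The interferon list had a mean log2 CPM of 4.41 in that library, 2.96 and 3.40 in control replicates 2 and 4, and 3.34, 2.87 and 3.63 in siRNA replicates 1, 2 and 5, so its fall depends on that control. Without siRNA replicate 5 the test called 3 lists, with a limma camera adjusted p of 0.408 for ATF4 targets, 0.0719 for DNA repair, 0.210 for p53 targets, 0.778 for oxidative phosphorylation and 0.719 for ribosomal proteins, which turned downward. Without siRNA replicate 2 it called 4, with 0.147 for interferon, 0.139 for p53 targets and 0.0788 for mitosis. Without control replicate 4 the limma camera adjusted p was 0.290 for mitosis, 0.118 for p53 targets and 0.0957 for oxidative phosphorylation, and without PANC1_siRBM3 replicate 3 it was 0.0579 for p53 targets.

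In PANC-1 no gene passed in edgeR, with 736 genes at an unadjusted p under 0.05 and 893 by chance. The smallest p-values belonged to RBM3, to PPP2R1B, a scaffold subunit of a serine/threonine phosphatase, at a log2 fold change of 0.78 (SE 0.17), to GSC, to MORF4L1 at -0.68 (SE 0.16) and to MCFD2 at 0.72 (SE 0.18). GSC, a homeobox transcription factor, had 24 counts in the siRNA libraries and 0 in the controls, at least 4.88-fold higher against a floor of 3 counts over the group. It was at 0.182, 0.155 and 0.402 CPM in siRNA replicates 1, 2 and 3 and at 0.944 CPM in MIA PaCa-2 with RBM3 siRNA. Without siRNA replicate 3, which also held MIA PaCa-2 transcripts, GSC had 11 counts against 0, at least 3.34-fold higher, and the bound was 2.96 without control replicate 1 and 3.10 without control replicate 4. PRR11 was at 19.2 ± 2.99 and 26.7 ± 6.2 CPM (SD, n = 3), a log2 fold change of 0.47 (SE 0.21) with an edgeR adjusted p of 0.9997 and an exact permutation p of 0.3. SKA2 was at 38.2 ± 4.4 and 46.1 ± 19.6 CPM (SD, n = 3). DESeq2 called RBM3, GJB5 and 1 gene without a symbol, and limma-voom called 0.

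PANC1_siRBM3 replicate 3 stood apart from the other PANC-1 libraries. COL1A2, a fibrillar collagen gene, was at 440.7 CPM in it, 0.673 ± 0.650 CPM in the other PANC-1 libraries (SD, n = 5) and 1400 ± 376 CPM in MIA PaCa-2 (SD, n = 6). ALDH1A1, a retinaldehyde dehydrogenase, was at 682 CPM in it, against 0.867 ± 0.763 (SD, n = 5) and 1312 ± 131 CPM (SD, n = 6). GJB5 had 457 counts in the PANC-1 siRNA group and 0 in the controls, all in that library, and the gene without a symbol called by DESeq2 had 1118 against 0, of which 1 remained without that library. Without that library, RBM3 had a log2 fold change of -1.72 (SE 0.30), PRR11 one of 0.32 (SE 0.23), PPP2R1B one of 0.72 (SE 0.19) and SKA2 one of -0.15 (SE 0.17). edgeR then still called no gene, and DESeq2 called RBM3. Without siRNA replicate 2, in which RBM3 was at 195 CPM against 96.5 and 83.0 CPM in the others, edgeR called RBM3, at -2.42 with an adjusted p of 0.00515.

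**Figure D2:**
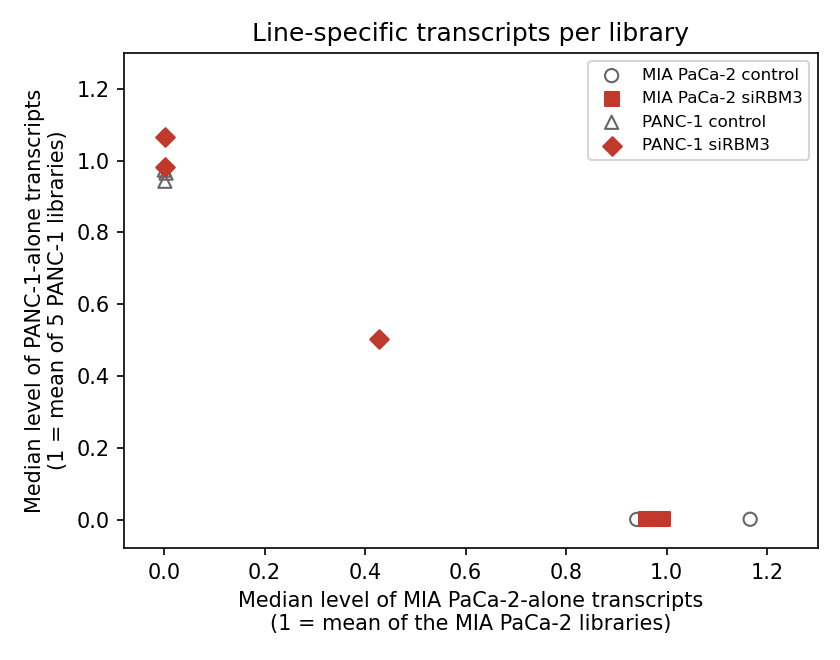
Median level, in each of the 12 libraries, of 44 transcripts found in MIA PaCa-2 alone (horizontal axis, 1 = mean of the MIA PaCa-2 libraries) and of 161 found in PANC-1 alone (vertical axis, 1 = mean of the other 5 PANC-1 libraries). PANC-1 siRNA replicate 3 lies at 0.427 and 0.503, while the other PANC-1 libraries lie at or under 0.00388 on the horizontal axis. The transcripts were chosen for being nearly absent from every library of the other line, this replicate left aside. The low values of the other libraries therefore follow from the choice.

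Of the 25 lists tested in PANC-1, camera called 3 at the preset correlation, all downward. Epithelial genes had a median log2 fold change of -0.32, with 17 of 19 negative (limma camera adjusted p 0.00138), including the keratins KRT8 at -0.43 (SE 0.25) and KRT19 at -0.44 (SE 0.25). Ribosomal protein genes had a median of -0.09, with 40 of 57 negative (limma camera adjusted p 0.00138), including RPS16 at -0.57 (SE 0.20). Oxidative phosphorylation genes had a median of -0.12, with 29 of 38 negative (limma camera adjusted p 0.00140), including COX6A1 at -0.62 (SE 0.26). The limma camera adjusted p with an estimated correlation was 0.934 for all 3. No list member passed in edgeR over all genes, and 1 passed adjusted over the list alone, COL1A2 in the fibroblast list, which was high in siRNA replicate 3. The siRNA libraries of PANC-1 were all deeper, at 31440551 to 33341322 counts, than the controls, at 14217185 to 23993638. The number of lists called was 9 without PANC1_control replicate 1, 5 without siRNA replicate 3 and 2 without siRNA replicate 1, where ribosomal proteins were at a limma camera adjusted p of 0.0573. The 9 lists without control replicate 1 were 4 upward and 5 downward. Those without siRNA replicate 3 included ATF4 targets, upward with a median of 0.15 (limma camera adjusted p 0.00639), the opposite of their direction in MIA PaCa-2. With an estimated correlation neither call held, at a limma camera adjusted p of 0.934 without that library and 0.888 in MIA PaCa-2. Over all libraries their median in PANC-1 was -0.01 (limma camera adjusted p 0.743), and they passed downward without control replicate 2 (0.0121) and with log2 total counts as a covariate (6.95e-07). Without siRNA replicate 2 mitosis genes passed upward (limma camera adjusted p 0.0320) and none of the 3 lists above passed, with a limma camera adjusted p of 0.228 for epithelial genes, 0.647 for ribosomal proteins and 0.653 for oxidative phosphorylation. Epithelial genes were also lost without control replicate 2 (limma camera adjusted p 0.228), and oxidative phosphorylation without control replicate 4 (0.135). The mean log2 CPM of the epithelial list was 3.95, 4.91 and 4.80 in control replicates 1, 2 and 4 and 4.85, 3.92 and 4.10 in siRNA replicates 1, 2 and 3, so siRNA replicate 1 lay within the range of the controls. Under control siRNA the epithelial list was higher in PANC-1 than in MIA PaCa-2, with a median log2 fold change of 1.92. The MIA PaCa-2 transcripts in siRNA replicate 3 could therefore lower this list in that library. RPS16 was also higher in PANC-1, so the same holds for it. Without siRNA replicate 3 the epithelial median was -0.21 (limma camera adjusted p 0.0346). With log2 total counts as a covariate, a fit added after the data were seen, epithelial genes were at a limma camera adjusted p of 0.273, and the direction turned upward for oxidative phosphorylation (0.875) and ribosomal proteins (0.000118).

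**Figure D3:**
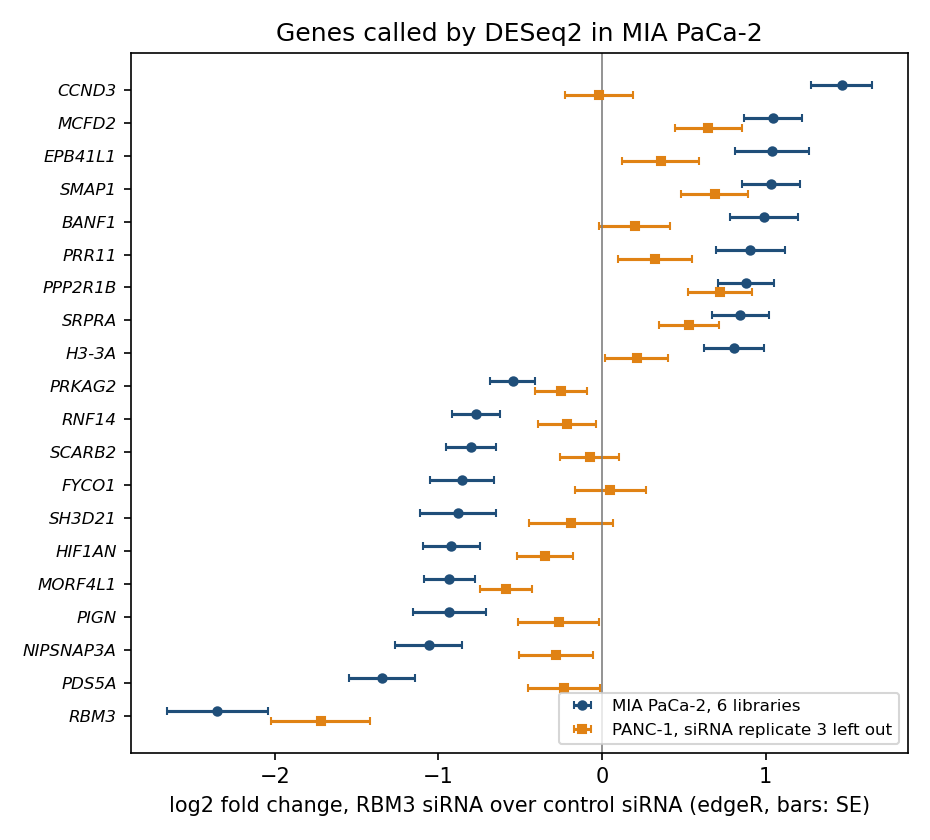
edgeR log2 fold change of RBM3 siRNA over control siRNA (horizontal axis) for the genes called by DESeq2 in MIA PaCa-2, pseudogene left out, in MIA PaCa-2 (blue circles) and in PANC-1 without siRNA replicate 3 (orange squares), with bars of 1 SE. CCND3 is at 1.46 in MIA PaCa-2 and -0.02 in PANC-1, while PPP2R1B is at 0.88 and 0.72.

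Whether RBM3 siRNA acted alike in the lines was asked by the overlap and by the difference of the responses. No gene was called in both lines by edgeR or limma-voom, and DESeq2 called RBM3 in both. Genes at an unadjusted edgeR p under 0.05 in both lines numbered 45 higher and 11 lower, against 11.7 and 0.839 for independent lists. Without PANC1_siRBM3 replicate 3 these were 31 and 5, against 2.19 and 1.42. Over the 11796 genes with a log2 CPM of at least 2, the log2 fold changes of the lines correlated at a Pearson r of 0.011 and a Spearman rho of 0.156. Without that replicate these were 0.083 and 0.108 over 11799 genes. Genes at an unadjusted edgeR p under 0.05 numbered 525 in MIA PaCa-2 and 736 in PANC-1, fewer than the 893 by chance. Spread between libraries may therefore make up most of these fold changes and lower the correlation. Low values thus cannot show that the responses differ. The lines have separate control libraries, but both tests used the same estimate of each gene's spread, and genes are not independent of each other. Counts expected for independent lists may therefore be too low. RBM3 itself is among the genes lower in both lines. Of the 20 genes other than RBM3 that DESeq2 called in MIA PaCa-2, 18 had the same sign in PANC-1 without that replicate, and 6 of the 20 had an unadjusted edgeR p under 0.05 there. These 6 included SMAP1 at 0.69 (SE 0.20) and SRPRA at 0.53 (SE 0.18). Both counts hold MORF4L1 and its pseudogene MORF4L1P1, whose reads could be split either way, so they may not be separate signals.

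For the difference between the responses edgeR called 0 genes, with 532 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 3. CCND3 had the smallest edgeR p, with a response in PANC-1 lower than in MIA PaCa-2 by a log2 value of -1.45 (SE 0.26). Its adjusted p was 0.9999 in edgeR and 0.00100 in DESeq2. The other DESeq2 calls were GJB5 and the gene without a symbol seen in PANC-1, both of which rest on PANC1_siRBM3 replicate 3; without that library DESeq2 called 1 gene, CCND3. The next smallest edgeR p-values were those of CASS4, at a difference of -2.99 (SE 0.70), GSC, MCMDC2 and FYCO1, at 1.06 (SE 0.28), each with an edgeR adjusted p of 0.9999. MCMDC2 was at 0.0290 ± 0.0319 and 0.596 ± 0.512 CPM in MIA PaCa-2 with control and RBM3 siRNA, and at 2.70 ± 0.833 and 2.46 ± 1.14 CPM in PANC-1 (SD, n = 3). RBM3 differed by 0.42 (SE 0.42), PRR11 by -0.43 (SE 0.30) and SKA2 by 0.23 (SE 0.34).

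Under control siRNA the lines differed widely. edgeR called 4644 genes higher and 4436 lower in PANC-1 than in MIA PaCa-2, 50.8% of those tested. The number of genes different between the lines under control siRNA was 9308 by DESeq2 and 8953 by limma-voom. FOXA2, a transcription factor of endoderm, was at least 1811-fold higher in PANC-1, where it had 4419 counts against 0. MFSD1, SPART, DDX43 and B3GALNT1 were at least 1594-fold, 1523-fold, 1202-fold and 1183-fold higher there, all against a floor of 3 counts over the group. Without MIAPaCa2_control replicate 1, the deepest library, the bounds of these 5 genes were 771, 678, 648, 512 and 504. In the other direction, the long non-coding RNA UCA1 had 8922 counts in MIA PaCa-2 and 3 in PANC-1, a ratio of 2419 (95% counting interval 827.5 to 11730). SLC17A9, a vesicular nucleotide transporter gene, had a ratio of 2315 (640.6 to 19120). All PANC-1 control counts of both genes were in replicate 1, and without it UCA1 was at least 1469-fold and SLC17A9 at least 937-fold higher in MIA PaCa-2, against 0 counts; without PANC1_control replicate 4 the ratios were 1536 and 1470. LINC01010, GJB5 and ZFP28 were at least 493-fold, 260-fold and 233-fold higher in MIA PaCa-2. LINC01010 was at 36.3, 9.49 and 9.46 CPM in MIA PaCa-2 control replicates 1, 2 and 4, and its bound was 188 without replicate 1. The bounds of these 3 genes were 300, 158 and 141 without PANC1_control replicate 1 and 313, 165 and 148 without PANC1_control replicate 4. RBM3 was higher in PANC-1 by a log2 value of 0.96 (SE 0.30, edgeR adjusted p 0.0163), a call lost without MIAPaCa2_control replicate 4 (0.86, edgeR adjusted p 0.0625) or PANC1_control replicate 1 (0.83). SKA2 was lower in PANC-1 by -1.18 (SE 0.24, edgeR adjusted p 0.00173), and PRR11 differed by -0.52 (SE 0.21, edgeR adjusted p 0.0553), a difference that passed without PANC1_siRBM3 replicate 2 (edgeR adjusted p 0.0362).

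PANC-1 was higher for both mesenchymal and epithelial genes. Of 19 mesenchymal genes 14 were higher and 1 lower in PANC-1, including the gelatinase gene MMP2, at 238 ± 49.0 against 0.05 ± 0.0670 CPM, SPARC, at 670 ± 291 against 0.637 ± 0.205, and the N-cadherin gene CDH2, at 39.4 ± 10.4 against 0.0369 ± 0.0329 (SD, n = 3). Of 19 epithelial genes 15 were higher and 1 lower, including EPCAM, at 27.6 ± 3.80 against 0.0527 ± 0.0484 CPM, and the splicing regulator ESRP2, at 29.4 ± 10.1 against 0.299 ± 0.102 (SD, n = 3). YAP target genes counted 12 higher and 2 lower of 21, among them CCN1 and TGFB2, and histone genes counted 7 higher and 0 lower of 8. Ribosomal protein genes counted 2 higher and 26 lower of 57, with RPS6 at -1.40 (SE 0.24) and RPS16 the other way at 2.17 (SE 0.20). Adjusted over the list alone, the higher and lower counts were 14 and 3, 15 and 1, 12 and 2, 7 and 0, and 2 and 26 for these lists in that order. camera in limma called all 5 at the preset correlation, with an adjusted p of 1.39e-06, 3.20e-05, 0.00615, 0.00242 and 0.00447. With an estimated correlation none was called, the limma camera adjusted p being 0.0993 for mesenchymal, 0.802 for epithelial and histone genes and 0.994 for YAP targets and ribosomal proteins. fry called 7 lists, with an adjusted p of 1.49e-05 for mesenchymal, 0.000408 for epithelial, 0.000359 for histone and 0.00650 for YAP genes. Ribosomal proteins did not pass (fry adjusted p 0.178). fry does not compare members with other genes, and 50.8% of all genes tested differed here.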

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

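The tests of the 3 patterns described here, the counts over other splits of the samples, the fits with total counts as a covariate or without PANC1_siRBM3 replicate 3, and the adjustment over 22 named genes were chosen only after the results were seen. The test of the difference between the responses of the lines was fixed before the data were examined.

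For 6 of the 22 named genes the edgeR p for a difference between the responses of the lines was under 0.05 when adjusted over those genes. The genes had been picked for their effect in a line or for that p, so this adjustment cannot show that the responses differ, and over all genes tested the edgeR adjusted p of each was 0.9999. CCND3, which encodes cyclin D3, had a response in PANC-1 minus that in MIA PaCa-2 of -1.45, with an edgeR adjusted p over the named genes of 0.00226. BANF1, a nuclear envelope protein, had a difference of -0.86 (0.0412 by the same edgeR test). FYCO1, an autophagosome transport adaptor, had 1.06 (0.0165) and PDS5A, a cohesin regulator, 1.02 (0.0165), again by edgeR. SCARB2, a lysosomal membrane protein, had 0.67 (edgeR 0.0412). GSC had a fitted difference of 5.89 (edgeR 0.0132), which rests on 24 counts against 0 in PANC-1 and depends on the prior count. Of these counts 11 remain without PANC1_siRBM3 replicate 3, where GSC was at 0.402 CPM and the MIA PaCa-2 share would bring 0.403 CPM.

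PANC1_siRBM3 replicate 3 held transcripts found in MIA PaCa-2 alone at a median share of 0.427 of their MIA PaCa-2 level, while those found in PANC-1 alone were at 0.503 of theirs. Both sets of transcripts were chosen for being nearly absent from every library of the other line, PANC1_siRBM3 replicate 3 left aside. The choice therefore kept the MIA PaCa-2 share low in the other siRNA libraries, at most 0.00203. It likewise kept the PANC-1 share low in the MIA PaCa-2 libraries, at most 0.000979. These values cannot decide on a response of PANC-1 cells to the siRNA or on an exchange of samples. The 0.503 in PANC1_siRBM3 replicate 3 was not fixed by the choice. A full exchange with a MIA PaCa-2 library would not leave it that high. The shares of 0.427 and 0.503 add to 0.93, about what MIA PaCa-2 RNA or reads in this replicate would give. When such RNA or reads entered was not tested. RBM3 was at 83.0 CPM there, under the 104 CPM that this share of MIA PaCa-2 control cells would bring alone (87.8 CPM at the lower quartile of the share, 0.359), so the MIA PaCa-2 part may come from siRNA-treated cells. With such a part taken out, PRR11 would be at 16.1 CPM, at 19.8 or 9.79 CPM with the lower or upper quartile of the share (0.359 and 0.513), and at 34.0 CPM if control cells were taken out, against 19.2 CPM in the PANC-1 controls, so its direction in the PANC-1 part of this library is left open.

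PANC1_control replicate 1 and PANC1_siRBM3 replicate 2 stood apart together, with BIRC3, an inhibitor of apoptosis under NF-kB control, at 558 and 635 CPM against 144, 109 and 139 CPM in control replicates 2 and 4 and siRNA replicate 1. The epithelial protease gene TMPRSS2 went the other way, at 1.75 and 2.42 against 19.2, 21.2 and 23.2 CPM. An exchange of these samples between the groups is argued against by RBM3, at 1.32 times the mean of the other controls in control replicate 1. Their median share of MIA PaCa-2 transcripts was at most 0.00388. Those transcripts were chosen for being nearly absent from these libraries among others, so the share cannot decide on MIA PaCa-2 RNA. Deviations of this pair from the group means correlated across genes with r = 0.687, the highest of 9 pairs. The pair was picked because it stood apart, centring 3 libraries on their mean forces some pairs up, and in MIA PaCa-2 control replicate 2 and siRNA replicate 5 reached 0.627, so this value does not decide for a shared batch or culture, which stays open. A difference between cultures that is biological was not tested, and no label names a batch; within these sets the log2 difference of RBM3 was -1.54 and -2.16, and that of PRR11 0.31 and 0.48.

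Ribosomal protein genes had a median log2 fold change of 0.09 in MIA PaCa-2 and -0.09 in PANC-1. In MIA PaCa-2 the list was lower in deeper libraries (Pearson r = -0.880, exact permutation p = 0.0167, adjusted over 2 relations 0.0333; Spearman rho = -0.829, exact permutation p = 0.0583), and r was -0.669 without the 2 libraries of most extreme depth. With total counts as a covariate the MIA PaCa-2 call held, at a limma camera adjusted p of 4.56e-08. The median went from 0.09 to 0.17 with that covariate, so the rise became larger, not smaller. In that fit this argues against depth as the cause of the rise in MIA PaCa-2. That rise depends on single libraries: without MIAPaCa2_control replicate 1 or siRNA replicate 5 the direction turned downward (limma camera adjusted p 0.110 and 0.719). In PANC-1, where r was -0.274 (exact permutation p = 0.576), the same fit turned the median to 0.18 (limma camera adjusted p 0.000118). That fit holds 1 slope for both lines, and within the groups r was 0.037 in PANC-1 against -0.954 in MIA PaCa-2, so the relation seen in MIA PaCa-2 was not seen within the PANC-1 groups. With 3 libraries per group and every siRNA library deeper than the controls, depth still cannot be told apart from the siRNA in PANC-1, while MIA PaCa-2 RNA in siRNA replicate 3 as the reason for the fall is argued against by the fall without it (median -0.23, limma camera adjusted p 3.90e-15). The fall depends on siRNA replicate 2, at a mean log2 CPM of 8.66 against 8.86 to 9.10 in the other PANC-1 libraries: without it the limma camera adjusted p was 0.647, and without siRNA replicate 1 it was 0.0573. With an estimated correlation the adjusted p was 0.888 and 0.934 by limma camera, and a response of ribosomal protein genes to RBM3 siRNA may not be needed to account for calls of this size.

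Other splits of the samples were run for each count. Within a line, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In MIA PaCa-2 the real split gave 2 genes and the highest other 0, and it gave 7 lists against 12, with 5 of the 10 splits giving as many lists. In PANC-1 the real split gave 0 genes and the highest other 51, that of control replicate 1 with siRNA replicates 2 and 3 against the rest, which points to a structure of the samples. For lists in PANC-1 the real split gave 3 and the highest other 13, with 8 of 10 giving as many. Between the lines under control siRNA the values were 9080 and 0 genes, with 1 of 10 splits giving as many. For the difference between the responses, 100 of 200 possible splits were drawn. The real value was 0 genes by edgeR and the highest other 66, from a split whose libraries were not recorded. For genes called in both lines these were 0 and 0. All 100 splits reach a count of 0, so they do not decide whether chance can be excluded.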

How the results depend on the processing

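The fit on genes with a symbol, those with sample weights, with total counts as a covariate or with the PANC-1 libraries set apart, and those of DESeq2 and of the estimated correlation without PANC1_siRBM3 replicate 3 are tests chosen only after the results were seen. The number of genes called in MIA PaCa-2 ranged from 0 to 86 over 27 settings, and 9080 genes between the lines from 6344 to 10983 over 24. Of 1074 comparisons of named genes with an alternative, 979 kept direction and side of the threshold, 21 lost the threshold, 61 gained it and 13 changed sign. A gene that passed in neither fit also counts as kept. Of the 21 losses, 16 were of CCND3 in MIA PaCa-2, over 25 settings. RBM3 and PRR11 within the lines are not among the 1074. RBM3 lost the threshold in 14 of 25 settings in MIA PaCa-2 and gained it in 6 of 25 in PANC-1. PRR11 gained it in 3 of 25 in MIA PaCa-2 and in 0 in PANC-1. Depth limits what can be seen: 3 counts are 0.211 CPM in the shallowest library. Except where a setting's construction is named, the cause was not tested.

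DESeq2 called 21 genes in MIA PaCa-2, 3 in PANC-1, 3 for the difference and 1 in both lines, with RBM3 at -1.95 in PANC-1 and PRR11 at 0.90 in MIA PaCa-2 past the threshold. limma-voom called 1 gene in MIA PaCa-2. Median-of-ratios size factors gave 0 there (RBM3 -2.36), as did the stricter filter (0, RBM3 -2.35) and a threshold of 0.01 (0). Without a filter, 230 genes were called in PANC-1, 107 for the difference and 1 in both lines (RBM3 -1.91 in PANC-1). Of the 229 higher ones in PANC-1, 208 were at least 5 times every other PANC-1 library in siRNA replicate 3. The lists called fell to 0 in MIA PaCa-2 and 0 in PANC-1 with an estimated correlation, and to 0 and 0 with fry.

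With the replicate number as a block, which keeps 8 libraries, MIA PaCa-2 gave 0 genes (RBM3 -2.71), the SKA2 log2 fold change in MIAPaCa2 was -0.019, that in PANC-1 -0.20 and the difference -0.18, and 5 lists were called in MIA PaCa-2 and 5 in PANC-1. Of the 7 MIA PaCa-2 calls, DNA repair and interferon passed, while the limma camera adjusted p was 0.261 for mitosis and p53 targets, 0.872 for ATF4 targets, 0.906 for ribosomal proteins and 0.921 for oxidative phosphorylation, which turned downward. In PANC-1 epithelial genes were lost (0.246 by limma camera) and ATF4 targets passed upward (1.55e-05). Deviations of same-numbered libraries from the group means correlated across genes at 0.28 and -0.15 in MIA PaCa-2 and at -0.54 and -0.44 in PANC-1. Centring few libraries on their mean moves such values, so they neither show nor exclude that the numbers pair the samples.

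With the PANC-1 libraries set apart and siRNA replicate 3 left out, 4 genes were called in MIA PaCa-2, 1 in PANC-1 and 1 in both, with RBM3 at -1.91 and SKA2 at -0.14 in PANC-1 and SKA2 at -0.18 for the difference. DESeq2 without that library called 29, 1, 1 for the difference and 1 in both, with RBM3 at -1.72 in PANC-1, PRR11 at 0.89 in MIA PaCa-2, and SKA2 at -0.14 in PANC-1 and -0.17 for the difference. Sample weights gave 86 genes in MIA PaCa-2, 1 in PANC-1 and 1 in both, with an RBM3 log2 fold change in PANC-1 of -2.10, PRR11 at 0.96 in MIA PaCa-2 and SKA2 at -0.14 for the difference. In MIA PaCa-2 siRNA replicate 2 had a weight of 6.22, against 0.957 and 0.491 for siRNA replicates 1 and 5. The siRNA side of the 86 calls therefore leaned on 1 library. Total counts as a covariate gave 0 in MIA PaCa-2 (RBM3 -2.35). The estimated correlation without siRNA replicate 3 gave 0 and 0 lists.

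Leaving out 1 library at a time gave 0 to 3 genes in MIA PaCa-2, 0 to 1 in PANC-1 and 0 to 1 in both lines. RBM3 ran from -2.59 to -2.20 in MIA PaCa-2, from -2.42 to -1.72 in PANC-1 and from -0.065 to 0.66 for the difference. SKA2 ran from -0.046 to 0.11 in MIA PaCa-2, from -0.15 to 0.44 in PANC-1 and from -0.19 to 0.40 for the difference. Lists called ran from 0 to 10 in MIA PaCa-2 and from 2 to 9 in PANC-1.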

Other observations

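The neighbour test of genes without a count and the use of genes with 1 to 20 counts are described last, and of the tests in this part only the latter, and the reading of the former, were chosen after the result was seen. Transcripts linked to RBM3 in earlier work, such as VEGFA, YAP1 and MCM3, gave no call as a list. VEGFA, the angiogenic growth factor, had a log2 fold change of -0.34 (SE 0.33) in MIA PaCa-2 and MCM3, a replication helicase subunit, -0.48 (SE 0.33). The limma camera adjusted p of the list was 0.384 in MIA PaCa-2 and 0.743 in PANC-1.

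Between the lines under control siRNA, 8 of 16 NF-kB response genes were higher and 3 lower in PANC-1 (9 and 3 adjusted over the list alone), though the list was not called (limma camera adjusted p 0.407, and 0.994 with an estimated correlation). ICAM1, an adhesion receptor, was at 316 ± 157 CPM in PANC-1 and 0.301 ± 0.193 CPM in MIA PaCa-2 (SD, n = 3). The chemokine gene CCL2 was at 270 CPM in PANC1_control replicate 1 but at 54.1 and 46.4 CPM in replicates 2 and 4, so its level depends on the library. Of 5 tested duct markers 3 were higher and 2 lower in PANC-1, and the list was not called (limma camera adjusted p 0.702). KRT19 was among the higher ones, at 1435 ± 480 against 341 ± 43.3 CPM (SD, n = 3). So was PDX1, a pancreatic transcription factor, at 7.10 ± 0.798 against 0.548 ± 0.536 CPM (SD, n = 3). COL1A2, of the fibroblast list, was lower, at 0.756 ± 0.830 in PANC-1 against 1507 ± 526 CPM (SD, n = 3). Of 12 leukocyte markers 5 and of 12 acinar markers 1 passed 1 CPM in any library. The 13 mitochondrially encoded genes had 0 counts in every library. Their reads may have been left out before or during counting, which was not tested, so their expression cannot be read from these counts.

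That siRNA seed matches lowered other transcripts in both lines was tested as a hypothesis. The siRNA sequences are not used here, so all 3097 stretches of 7 bases in RBM3 transcripts were scored by how far genes carrying them in the 3' untranslated region were lower in both lines. The best score was -2.57 against a median of -2.20 in 1000 random sets, and a share of 0.239 of the sets scored as low. Seed effects may or may not be present, since this share reaches neither bound set before the data were examined.

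Loss of chromosome segments as the reason why lines lack transcripts was tested by asking whether genes without a count lie next to each other. Here and for the set described below, only protein-coding genes expressed in the other line were taken, and PANC1_siRBM3 replicate 3 was left aside. With 17 genes without a count in MIA PaCa-2 and 1 in PANC-1 there were 0 neighbouring pairs. The share of 10000 random sets with fewer pairs was 0. The 1 gene in PANC-1 was GJB5, which had 457 counts in the library left aside. The bound written beforehand, a count no higher than the random median, was met, but it was wrong for so few genes: the random median is 0, no lower count exists and 1 gene makes no pair. Loss of chromosome segments could therefore be neither shown nor excluded. Among genes with 1 to 20 counts, a set examined after this, there were 26 pairs in MIA PaCa-2 (random median 6, highest 16) and 6 in PANC-1 (random median 0, highest 3), which shared silencing of neighbours would give as well.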
